A study of Rattus norvegicus with 23 samples.

How the data were processed

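RNA-seq was measured in 23 libraries from healthy tissues and repaired median nerves of adult female rats. Per the labels' protocols, RNA was extracted with TRIzol, mRNA was selected with poly-T beads from 350 ng of total RNA, and non-directional libraries were sequenced on an Illumina instrument. The kit does not mark strand, so reads from overlapping sense and antisense genes cannot be told apart. Per the submitters' processing notes, CASAVA and HISAT2 were used, with no version given. The counting tool, the genome build and the annotation are not given in the sources used here, nor is the treatment of reads shared by paralogs, so genes with near-identical copies have uncertain counts. The authors deposited 1 table of raw counts per gene identifier and library, whole numbers that sum to different totals per library and were not normalized. All 23 columns matched a library title, and 0 columns were left over.

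The rows carry Ensembl rat gene identifiers. The reference gene table used here (assembly GRCr8, 47357 rows) holds an Ensembl identifier in 0 rows, and 0 of the 32545 identifiers matched a symbol. For this reason the 37 gene lists fixed by symbol before the data were examined could not be measured (0 lists had a measured member), and no gene names or positions are printed. The rule for named genes, also fixed before the data were examined, asked for an adjusted p under 0.05, a mean of at least 10 CPM in the higher group, no overlap between the groups' libraries and a gene symbol, in order of log2 fold change. No gene passes its symbol clause. The text names up to 2 identifiers in each direction from the same order without that clause, and 2 more from outside the muscle-enriched genes for MIV against EV over both days.

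Libraries were grouped by their titles. Library totals ranged from 12504035 to 17314324 counts. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr with a minimum count of 10 and a minimum total of 15, TMM factors, robust glmQLFit and glmQLFTest, 1 coefficient per group, Benjamini-Hochberg adjustment, threshold 0.05). Comparisons among repaired nerves used the 12 repaired libraries (15036 genes, biological coefficient of variation 37.1%), and those with healthy tissues used all 23 (15954 genes, 31.4%). CPM values use the library sizes times the TMM factors. Log2 CPM for set tests, correlations and components used a prior count of 2. Where a group had 0 counts, a fold is a lower bound against 3 counts over the group, which covers counting error only.

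Muscle-enriched genes, planned before the data were examined, had a log2 fold change above 1 and an adjusted p under 0.05 against both other healthy tissues. Nerve- and vein-enriched genes (the same rule) and repair-induced (1216) and repair-reduced (421) genes were defined after the data had been examined, because the identifiers matched no symbol. The latter 2 groups had a mean over the 4 repaired groups that was more than 1 log2 unit above, or below, each of the 3 healthy tissues with an adjusted p under 0.05. Gene groups were tested with camera (preset correlation 0.01, and estimated correlation) and fry from limma 3.58.1, adjusted over the groups of a comparison. Shares of counts were compared with two-sided exact permutation tests. The smallest p is 0.1 for 3 against 3 libraries and 0.005 for 400 permutations within days.

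The tests were checked on counts simulated from the real means and dispersions with 200 changed genes. Changed genes were drawn only from those above a minimum mean level in every compared group, and the libraries of a group shared a common mean. The recovered shares therefore do not cover genes that are nearly absent from a group, or a library that stands apart. For MIV against EV at day 7 (15036 genes), 11.9% of genes changed 2-fold, 76.1% of those changed 4-fold and 93.9% of those changed 8-fold were recovered, with 6 false calls among 14836 unchanged genes. At day 3 the shares were 13.4%, 73.1% and 84.8%. For the contrast over both days they were 64.2%, 95.5% and 95.5%, and for EV at day 3 against healthy nerve (15954 genes) 62.7%, 94.0% and 98.5%. In a simulation of MIV against EV at day 7 with only the muscle-enriched genes raised 1.5-fold, the unchanged vein-enriched genes came out at a median log2 fold change of -0.09, and fry called them lower (adjusted p = 0.000147), as did camera with an estimated correlation (adjusted p = 0.00120), while camera at the preset correlation did not (adjusted p = 0.135). The unchanged nerve-enriched genes came out at -0.13 and were called lower by all 3, camera at the preset correlation included (adjusted p = 0.0277, 6.79e-05 with an estimated correlation and 6.58e-06 with fry). Small shifts of a group can therefore follow from the scaling alone. The simulated genes varied independently of each other, whereas the real sets had estimated correlations of 0.134 (vein-enriched) and 0.0422 (nerve-enriched). The p-values of the simulated set tests therefore do not carry over to the data.

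Replicate pairs were compared by chi-square. Over 28 pairs within groups the smallest chi-square per degree of freedom was 14.9, so no library was a copy of another in its group. Pairs from different groups were not compared this way. The replicate numbers in the titles were checked by correlating the deviations of log2 CPM from the group means. Between EV and MIV at day 7 the 3 same-numbered pairs correlated at 0.176 to 0.224, all over the limit of 0.1 set for treating numbers as pairs, so a block for the number at day 7 was added. None of the other 5 pairs of repaired groups met the limit, 1 of the 36 possible matchings of libraries did, and no label says what a number shares, so the pairing comes from the data alone. Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE factors, no filter on low counts, a replicate block, TMM factors from genes that were not muscle-enriched, fits of the 2 compared groups alone, all 23 libraries in 1 fit, other thresholds for muscle-enriched genes, shares without the 10 genes with the most counts and each library left out in turn. Voom with sample quality weights in limma, the block at day 7 and the contrast over both days were added after the data had been examined.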

Results

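The data comprise gene-level read counts from 23 rat RNA-seq libraries in 7 groups. The median nerves of adult female rats had been cut to leave an 8 mm gap. The series design describes repair with a 10 mm muscle-in-vein graft, a piece of vein filled with skeletal muscle that bridges the gap as a conduit. Regenerating nerves were collected after 3 and 7 days from a series labelled MIV (n = 3 at each day) and a series labelled EV (n = 3 at each day), whose treatment label names repair of the cut and does not name MIV. Healthy median nerve (n = 5), adductor muscle (n = 3) and epigastric vein (n = 3) served as untreated reference tissues. Library totals ranged from 12504035 to 17314324 counts over 32545 gene identifiers, of which 9099 had no count in any library. No label says that the libraries came from separate animals, so p-values measure the spread between these samples. The identifiers could not be paired with gene names here, so the results are given as groups of genes defined by the tissue that carried them, with at most 2 identifiers in each direction per comparison.

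The principal components of log2 counts scaled to sequencing depth (log2 CPM) separated the 3 healthy tissues from each other and from the repaired nerves. Component 1 held 35.8% of the variance, with the healthy muscle libraries at one end, and component 2 held 32.0%, with healthy nerve at one end. Replicates correlated at 0.952 or more across genes in 6 of the groups, and at 0.874 to 0.952 in the MIV day 7 group. MIV day 7 replicate 3 lay towards healthy muscle, whereas replicate 2 lay among the EV and MIV day 3 libraries.

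**Figure D1:**
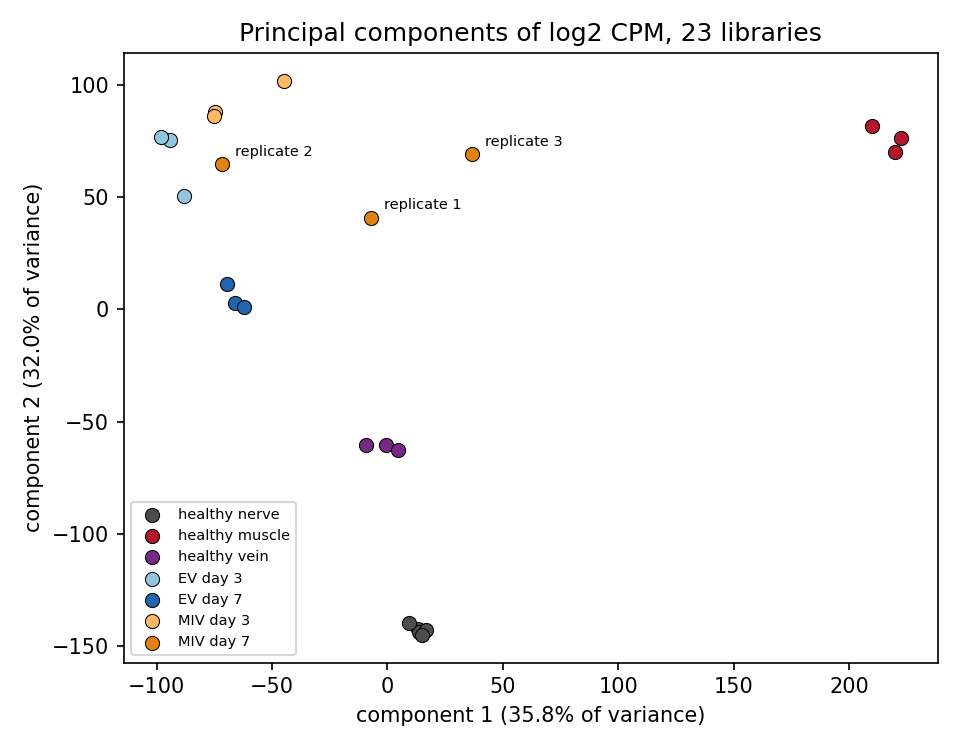
Each point is 1 library, placed by the first and second principal components of log2 CPM (axis units are component scores), with groups in colour and the MIV day 7 replicates numbered. The 3 MIV day 7 libraries are spread along component 1, which holds 35.8% of the variance.

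The healthy tissues were compared first to learn which transcripts each tissue carries. Muscle carried 5024 genes at a higher level than nerve and 5716 at a lower level, out of 15954 tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. Against vein, muscle was higher for 4912 and lower for 5334, and vein was higher than nerve for 3014 and lower for 3421. ENSRNOG00000049695 reached 191518 CPM ± 15430.5 (SD, n = 3) in muscle and 0.0609 CPM ± 0.0588 (SD, n = 5) in nerve (edgeR adjusted p = 1.27e-08). ENSRNOG00000022707 stood at 729 CPM ± 273 (SD, n = 5) in nerve and had no count in vein, which makes it at least 12871-fold lower there (edgeR adjusted p = 1.73e-08). With scaling factors taken only from genes that were not muscle-enriched, the share of calls that were higher in muscle went from 46.8% to 59.1% against nerve and from 47.9% to 60.9% against vein, and the median log2 fold change of all genes shifted by 0.39 and 0.38. With DESeq2 the median shifted by 0.19 and 0.16.

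Genes at more than 1 log2 unit above both other healthy tissues numbered 2842 for muscle, 1485 for nerve and 1127 for vein. The muscle-enriched genes took 80.4% ± 0.361 (SD, n = 3) of the counts in muscle, 15.9% ± 1.18 (SD, n = 5) in nerve and 16.5% ± 0.708 (SD, n = 3) in vein. The nerve-enriched genes took 26.3% ± 1.55 (SD, n = 5) of the counts in nerve and 0.677% ± 0.0457 (SD, n = 3) in muscle. The vein-enriched genes took 17.9% ± 1.35 (SD, n = 3) of the counts in vein and 3.71% ± 0.234 (SD, n = 5) in nerve. All 3 groups were defined on these libraries, so their levels in the tissue that defined them are not independent evidence. Each group was also selected as lower in the other 2 healthy tissues, which favours a rise of that group in any comparison with them.

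**Figure D2:**
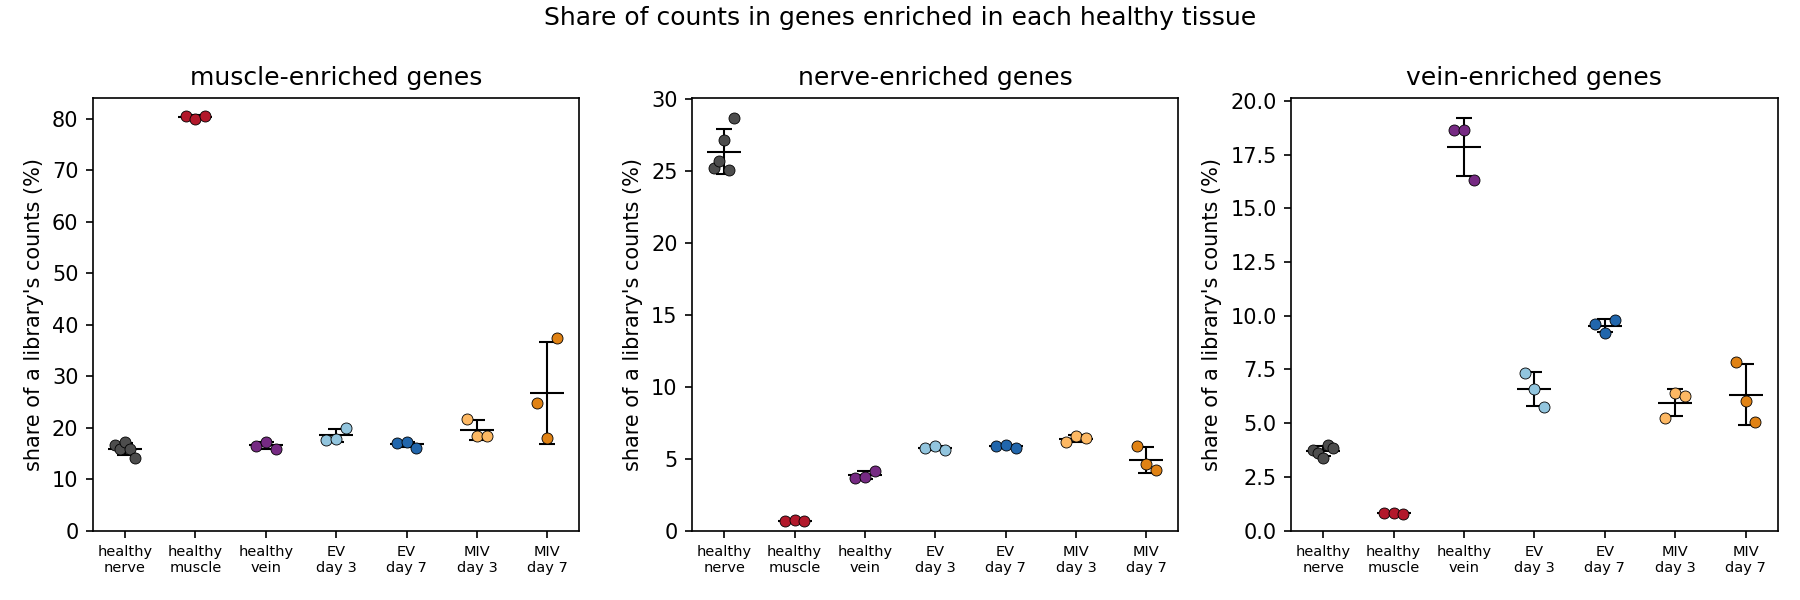
The vertical axes give the share of a library's counts (%) in muscle-, nerve- and vein-enriched genes, with 1 point per library, a horizontal bar at the group mean and error bars of 1 SD. The muscle-enriched share of the MIV day 7 libraries runs from 17.9% to 37.4%, and the EV day 7 libraries sit between 16.1% and 17.1%.

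The MIV and EV nerves were compared at each day to address the series' question on the role of muscle fibres in early regeneration in the graft. At day 7, muscle-enriched genes lay higher in MIV: 86.6% of the 2697 measured had a positive log2 fold change, with a median of 0.41 and quartiles of 0.16 and 0.85. Vein-enriched genes lay lower, with a median log2 fold change of -0.55 over 1065 genes, 18.1% of them positive. As sets, muscle-enriched genes were higher and vein-enriched genes lower with camera at a preset correlation (adjusted p = 2.31e-38 and 2.75e-19). Neither call held with an estimated correlation (adjusted p = 0.0799 for both), while fry, which tests whether a set moves one way, gave an adjusted p of 0.0337 for both. In counts simulated with only the muscle-enriched genes raised 1.5-fold, fry also called the unchanged vein- and nerve-enriched genes lower, at median log2 fold changes of -0.09 and -0.13. Genes were independent in that simulation and are correlated in the data, so its p-values do not bear on the real ones. The real vein-enriched median of -0.55 lay beyond the simulated shift of -0.09. Nerve-enriched and repair-reduced genes passed lower at the preset correlation at day 7 (medians -0.10 and -0.16, adjusted p = 0.0192 and 0.0127) but not with an estimated correlation (adjusted p = 0.429 and 0.669) or with fry (adjusted p = 0.197 and 0.4999). With the replicate number as a block at day 7, added after the data had been examined, the nerve-enriched set passed fry (adjusted p = 0.0244, median -0.15). In the simulation the unchanged nerve-enriched genes had a similar median (-0.13), so a shift of this size can follow from scaling alone. A change in nerve-enriched genes therefore cannot be told apart from scaling here. At day 3 the median log2 fold changes were 0.05 for muscle-enriched and -0.25 for vein-enriched genes. Both day 3 sets also passed only at the preset correlation (adjusted p = 4.54e-05 and 2.57e-06) and not with an estimated correlation (adjusted p = 0.824 for both) or with fry (adjusted p = 0.852 for both).

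No single gene passed edgeR's quasi-likelihood test between MIV and EV at either day, out of 15036 tested in the 12 repaired nerves without a block. With the replicate number as a block at day 7 alone, added after the data had been examined because same-numbered EV and MIV libraries deviated together on that day, 36 genes were higher and 7 lower in MIV at day 7, 28 of them muscle-enriched. The same block called 4 genes with the 2 groups alone, and a block of the number over both days called 0. At an unadjusted p under 0.05, 558 genes were higher and 217 lower in MIV at day 3, close to the share of 0.05 of the 15036 genes that chance alone gives. At day 7, 1476 were higher and 1038 lower, above that share. DESeq2 called 239 genes at day 3 (225 higher, 14 lower) and 824 at day 7 (623 higher, 201 lower). EdgeR fitted over all 23 libraries called 160 at day 3 and 1135 at day 7. That fit had a biological coefficient of variation of 31.4%, against 37.1% in the 12 repaired nerves, so it may understate their spread. Voom with quality weights in limma, added after the data had been examined, called 30 and 414. Of the DESeq2 calls, 124 at day 3 and 498 at day 7 were muscle-enriched, which left 115 and 326 outside that group. Adjusted over the list alone, edgeR called 487 muscle-enriched genes at day 7 and 1 at day 3. The counts of 0 depended on single libraries. Without MIV day 7 replicate 2 edgeR called 70 genes at day 3 (28 outside the muscle-enriched genes) and 688 at day 7 (649 higher, 39 lower, 151 outside). At day 7, edgeR called 45 genes without MIV day 3 replicate 1, 16 without MIV day 7 replicate 1 and 1 without MIV day 7 replicate 3, whose omission gave 2 at day 3. The difference between the MIV effects of the 2 days gave no call with edgeR, 16 calls with DESeq2, 0 with voom and 3 with edgeR without MIV day 7 replicate 2. At an unadjusted p under 0.05 it gave 796 genes, again close to the share that chance alone gives. For this difference the muscle-enriched genes had a median of 0.36 on the log2 scale and passed at the preset correlation (adjusted p = 7.55e-22), but not with an estimated correlation (adjusted p = 0.235) or with fry (adjusted p = 0.273).

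The muscle-enriched share of counts was 19.5% ± 1.93 in MIV and 18.5% ± 1.25 in EV at day 3 (SD, n = 3 each), a difference of 1.004 percentage points (two-sided exact permutation p = 0.5). At day 7 it was 26.7% ± 9.87 in MIV and 16.7% ± 0.557 in EV (SD, n = 3 each), a difference of 9.96 percentage points with every MIV library above every EV library, which chance gives in 10% of cases counting both directions (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). With labels permuted within each day, the difference over both days was 5.48 percentage points (two-sided exact permutation p = 0.06, with 0.005 the smallest possible, and adjusted p = 0.15 over the 5 gene groups). Without MIV day 3 replicate 1, which held 21.7%, the day 3 difference was -0.107. The day 7 difference was 4.61 without MIV day 7 replicate 3 and 14.3 without replicate 2. With only genes at more than 2 log2 units above both other tissues, day 7 again had no overlap. The share ran from 10.6% to 28.7% in MIV and from 9.15% to 10.05% in EV, while the day 3 shares overlapped. Counting only genes at more than 3 log2 units above both other tissues reversed which day was without overlap. The share was then 10.2% ± 8.25 in MIV and 2.66% ± 0.0793 in EV at day 7 (SD, n = 3 each; exact permutation p = 0.4), with the lowest MIV library at 2.599% and the lowest EV library at 2.602%. At day 3 it was 4.43% ± 1.18 and 3.07% ± 0.336 (SD, n = 3 each; exact permutation p = 0.1), with every MIV library above every EV library. The vein-enriched share was 6.32% ± 1.41 in MIV and 9.53% ± 0.298 in EV at day 7 (SD, n = 3 each), again without overlap (exact permutation p = 0.1). At day 3 it was 5.95% ± 0.639 in MIV and 6.57% ± 0.799 in EV, with overlap (SD, n = 3 each; exact permutation p = 0.4). The difference over both days was -1.92 percentage points (exact permutation p = 0.02, adjusted p = 0.1). The nerve-enriched share was 6.39% ± 0.216 in MIV and 5.72% ± 0.152 in EV at day 3 (SD, n = 3 each), and 4.90% ± 0.891 against 5.84% ± 0.0977 at day 7 (exact permutation p = 0.1 and 0.3).

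A contrast over both days, chosen after the separate days had been examined, gave 214 genes that rose and 18 that fell in MIV relative to EV (edgeR, adjusted p under 0.05). Of the genes that rose, 157 were muscle-enriched, and of those that fell none were, which left 57 rises and 18 falls outside that group. Among these, 17 rises and 1 fall were nerve-enriched (1164 measured), and 2 rises and 9 falls were vein-enriched (1065 measured). ENSRNOG00000008536, a muscle-enriched gene, stood at 1208 CPM ± 1564 in MIV and 0.0357 CPM ± 0.0395 in EV (SD, n = 6 each; edgeR adjusted p = 0.00467), with 2042 to 50898 counts per MIV library and 0 to 1 per EV library. ENSRNOG00000046276, also muscle-enriched, stood at 594 CPM ± 711 and 0.123 CPM ± 0.202 (SD, n = 6 each; log2 fold change 12.31 ± 1.29 SE, edgeR adjusted p = 0.0110), with 1311 to 22932 counts per MIV library and 0 to 7 per EV library. The falls were smaller: the vein-enriched genes ENSRNOG00000010063 and ENSRNOG00000007027 changed by -1.28 ± 0.24 and -0.85 ± 0.12 on the log2 scale (SE; edgeR adjusted p = 0.0272 and 0.0111).

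Compared with healthy muscle in the 23-library fit, 124 of the 157 muscle-enriched genes that rose were lower in the MIV nerves, 22 did not pass and 11 were higher. With scaling factors from genes that were not muscle-enriched, all 11 kept a positive log2 fold change (median 2.62 against 2.93), and 7 stayed called higher. Over all 2842 muscle-enriched genes, 37 were higher in MIV than in healthy muscle. The 100 muscle-enriched genes most abundant in healthy muscle were all lower in MIV, which their choice by level in healthy muscle favours. Of these 100, 37 were among the 157.

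**Figure D3:**
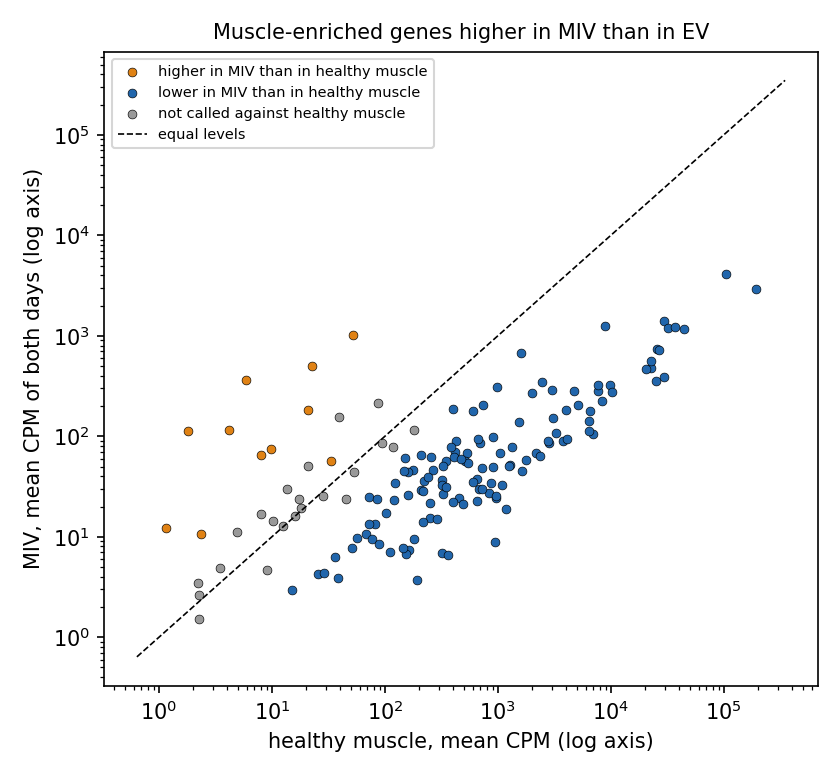
Each point is 1 of the 157 muscle-enriched genes that rose in MIV relative to EV over both days, with mean CPM in healthy muscle on the horizontal and mean CPM in MIV on the vertical axis (both log axes); colours give the test against healthy muscle and the dashed line marks equal levels. The 11 genes above healthy muscle lie above the line and the 124 below it lie under the line.

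The count over both days was sensitive to single libraries and to the method. EdgeR called 0 genes without EV day 3 replicate 1 or 3 or EV day 7 replicate 1 or 3, 2 without EV day 7 replicate 2, 64 without EV day 3 replicate 2, 109 without MIV day 3 replicate 1, 126 without MIV day 7 replicate 3 and 698 without MIV day 7 replicate 2, which included all 232 genes called with it. DESeq2 called 820 genes, 73.8% of them higher against 92.2% with edgeR, and 231 of the 232 were among them. EdgeR fitted over all 23 libraries, which may understate the spread of the repaired nerves, called 975, and voom with quality weights in limma called 480.

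The time course in the repaired nerves was compared within each series. From day 3 to day 7, 1415 genes rose and 1532 fell in EV, and 1111 rose and 1216 fell in MIV (edgeR, adjusted p under 0.05, 15036 tested). The 2 series, which share no library in these contrasts, had 702 rising genes in common, against 105 for independent lists, and 861 falling genes in common against 124. Only 1 gene called in both series went in opposite directions. Across genes, the fold changes of the 2 series correlated with a Pearson r of 0.736 and a Spearman rho of 0.705 (genes are not independent replicates).

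Genes lower in the repaired nerves than in all 3 healthy tissues, called repair-reduced, had positive log2 fold changes from day 3 to day 7 for 94.0% of genes in EV and 92.02% in MIV: in EV 122 of 351 measured rose and 1 fell, with a median log2 fold change of 1.21, and in MIV 107 rose and 2 fell, also with a median of 1.21. Their share of counts went from 0.448% ± 0.0591 to 1.21% ± 0.0628 in EV (SD, n = 3 each; exact permutation p = 0.1), against 9.01% ± 1.10 in healthy nerve (SD, n = 5). Genes higher in the repaired nerves than in all 3 healthy tissues, called repair-induced, fell more often than they rose: 339 of 1216 fell, 32 rose and 845 were not called in EV (median log2 fold change -0.84), and 341 fell, 38 rose and 837 were not called in MIV (median -0.49). Their share of counts was 15.4% ± 0.922 and 15.2% ± 0.603 at days 3 and 7 in EV (exact permutation p = 0.9) and 15.8% ± 0.752 and 15.95% ± 5.54 in MIV (SD, n = 3 each; exact permutation p = 1). Of the vein-enriched genes, 263 of 1065 rose and 29 fell in EV (median 0.73), and in MIV 165 rose and 46 fell (median 0.50). Of 1164 nerve-enriched genes, 210 rose and 86 fell in EV, and 138 rose and 103 fell in MIV. Of 2697 muscle-enriched genes, 396 fell and 89 rose in EV, and 119 fell and 219 rose in MIV. The difference between the series was tested as the interaction above, which called no gene.

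As sets, the repair-reduced and repair-induced genes passed camera at the preset correlation in both series but not with an estimated correlation (adjusted p = 0.146 in EV and 0.154 in MIV), while fry gave adjusted p of 0.00243 and 0.00380 in EV and 0.00657 for both in MIV. The vein-enriched set passed fry in EV (adjusted p = 0.00553) and did not in MIV (adjusted p = 0.164). With an estimated correlation it did not pass in either (adjusted p = 0.146 and 0.570). Nerve-enriched genes in EV passed fry (adjusted p = 0.0152) and not with an estimated correlation (adjusted p = 0.219). In MIV they passed none of the tests (adjusted p = 0.407 at the preset correlation, 0.687 with an estimated correlation and 0.570 with fry). Muscle-enriched genes passed only at the preset correlation, and neither with fry nor with an estimated correlation, in EV (adjusted p = 0.208 and 0.457) and in MIV (adjusted p = 0.542 and 0.687). These repair groups were defined on the same repaired libraries, although on the mean of all 4 repaired groups and not on the days. ENSRNOG00000005348, a nerve-enriched gene, went from 0.769 CPM ± 0.784 to 61.7 CPM ± 17.8 in EV (SD, n = 3 each; log2 fold change 6.35 ± 1.05 SE, edgeR adjusted p = 0.00335). ENSRNOG00000002916 fell in both series, by 6.26 ± 1.03 SE on the log2 scale in EV (edgeR adjusted p = 0.00331) and by 6.83 ± 1.07 SE in MIV (edgeR adjusted p = 0.00293). ENSRNOG00000050042, a muscle-enriched gene, went from 2.47 CPM ± 2.05 to 859 CPM ± 1219.6 in MIV (SD, n = 3 each; edgeR adjusted p = 0.0129), with 20 to 83 counts per library at day 3 and 354 to 26943 at day 7, where 1 library held 26943 of the 31594 counts.

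The EV count was 1390 to 1868 when any 1 EV library was left out except EV day 3 replicate 1, that is 1390 and 1585 without EV day 3 replicates 2 and 3 and 1611, 1868 and 1497 without EV day 7 replicates 1, 2 and 3. The MIV count was 938 and 804 without MIV day 3 replicates 2 and 3, 1463 without MIV day 7 replicate 1 and 3569 without MIV day 7 replicate 2.

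**Figure D4:**
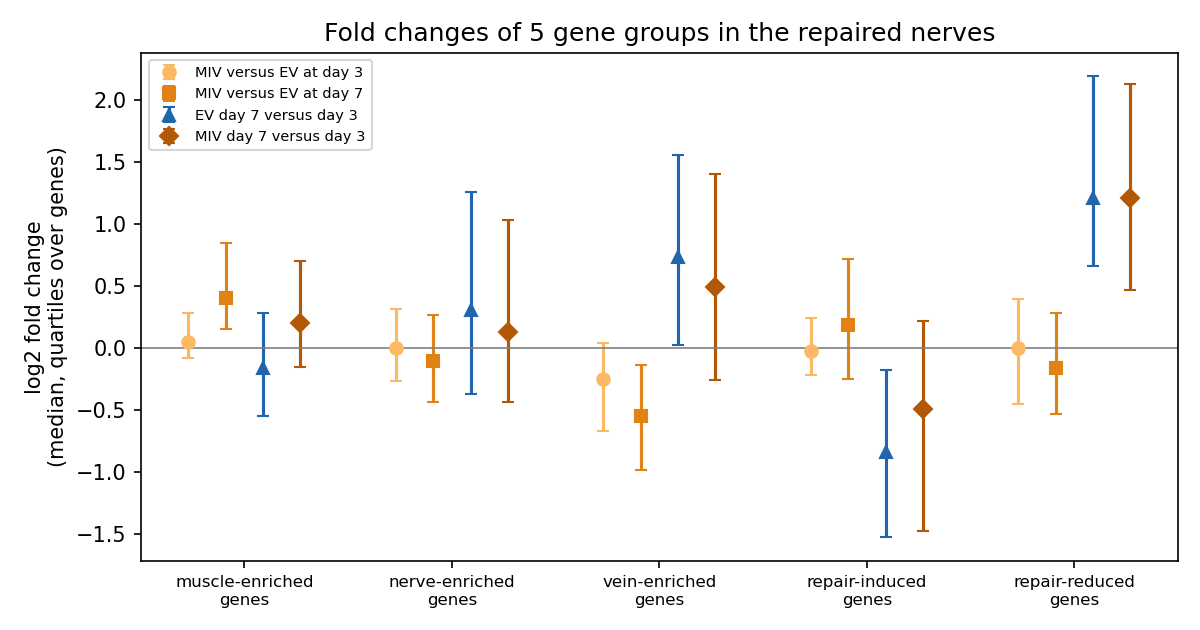
Points give the median log2 fold change (vertical axis) of 5 gene groups in 4 comparisons of repaired nerves, and bars run from the lower to the upper quartile over genes. Repair-reduced genes have a median of 1.21 between days in both series, and vein-enriched genes have a median of -0.55 between MIV and EV at day 7.

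Repaired nerves were set against healthy nerve. The samples may differ in tissue content as well as in their response to injury and repair. The counts below cannot tell these apart. Nerve-enriched genes fell in all 4 groups. In EV 1193 of 1485 fell and 92 rose at day 3 (median log2 fold change -2.81), and 1156 fell and 54 rose at day 7 (median -2.28). In MIV 1166 fell and 100 rose at day 3 (median -2.68), and 1151 fell and 66 rose at day 7 (median -2.33). The 4 set tests held with an estimated correlation (camera adjusted p = 2.58e-06, 3.73e-07, 3.48e-06 and 4.44e-07), but the group was defined on the same healthy nerves. Vein-enriched genes were higher than in healthy nerve in EV at day 7, with 717 of 1127 higher and 43 lower (median log2 fold change 1.35, adjusted p = 0.00637 with an estimated correlation), a rise that the selection of the group as lower in these nerves favours. In MIV at day 7, 495 were higher and 111 lower (median 0.75, adjusted p = 0.152 with an estimated correlation). At day 3, 471 were higher and 207 lower in EV, and 412 higher and 274 lower in MIV (adjusted p = 0.408 and 0.509 with an estimated correlation).

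Muscle-enriched genes differed from healthy nerve in both directions at day 3 of EV, with 883 of 2842 higher and 606 lower, and at day 7, with 458 higher and 587 lower. In MIV 1110 were higher and 524 lower at day 3, and 1309 higher and 273 lower at day 7. None of the muscle-enriched sets passed with an estimated correlation (adjusted p = 0.626 and 0.884 in EV, 0.509 and 0.152 in MIV). In all, 4783 genes were higher and 4899 lower than in healthy nerve in EV at day 3, and 3841 and 3822 at day 7. The MIV counts were 4927 and 4876 at day 3, and 4654 and 4046 at day 7 (edgeR, 15954 genes tested).

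ENSRNOG00000003171, a nerve-enriched gene, stood at 36330.2 CPM ± 12080.4 in healthy nerve (SD, n = 5), at 0.944 CPM ± 0.375 in EV (edgeR adjusted p = 2.57e-06) and at 0.698 CPM ± 0.508 in MIV at day 3 (SD, n = 3 each; edgeR adjusted p = 2.11e-06). ENSRNOG00000048139, also nerve-enriched, had 495 CPM ± 66.1 in healthy nerve and no count in MIV at day 3, at least 9595-fold lower (edgeR adjusted p = 8.04e-11). ENSRNOG00000002548 stood at 233 CPM ± 23.1 in EV at day 3 (SD, n = 3) and 0.133 CPM ± 0.166 in healthy nerve (SD, n = 5; edgeR adjusted p = 3.90e-09). ENSRNOG00000030187 stood at 178 CPM ± 123 in EV at day 7 (SD, n = 3) and 0.0492 CPM ± 0.110 in healthy nerve (SD, n = 5; edgeR adjusted p = 8.72e-08). ENSRNOG00000008536 had no count in healthy nerve and was at least 13850.3-fold higher in MIV at day 3 and at least 39998-fold higher at day 7 (edgeR adjusted p = 2.36e-07 and 1.92e-07).

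The MIV nerves were also set against healthy muscle, the tissue placed in the graft. Of the 2842 muscle-enriched genes, 2570 were lower and 48 higher in MIV at day 3 (median log2 fold change -2.17), and 2559 were lower and 30 higher at day 7 (median -1.93). Both sets held with an estimated correlation (camera adjusted p = 0.000573 and 0.000326), on a group defined by these muscle libraries. Nerve-enriched genes were higher than in muscle, 661 of 1485 at day 3 and 754 at day 7, with 177 and 82 lower (adjusted p = 0.0177 and 0.00362 with an estimated correlation), on a group selected as lower in these muscle libraries. Vein-enriched genes were higher for 557 of 1127 at day 3 and 735 at day 7, with 121 and 33 lower (adjusted p = 0.101 and 0.0216 with an estimated correlation), under the same selection. ENSRNOG00000049124 had 320.4 CPM ± 129 in healthy muscle and no count in MIV at day 7 (SD, n = 3 each), at least 4967-fold lower (edgeR adjusted p = 1.43e-06). ENSRNOG00000030187 had no count in muscle and 94.5 CPM ± 46.03 in MIV at day 3 (SD, n = 3), at least 591-fold higher (edgeR adjusted p = 2.87e-06).

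Over all genes, 5338 were higher and 5263 lower in MIV than in muscle at day 3, and 5540 and 4999 at day 7. With scaling factors from genes that were not muscle-enriched, the share of calls that were higher fell from 50.4% to 39.9% at day 3 and from 52.6% to 42.9% at day 7, and the median log2 fold change of all genes shifted by -0.34 and -0.29. With DESeq2 the day 7 median shifted by -0.17.

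The EV nerves were compared with healthy vein. Vein-enriched genes were lower in EV, 706 of 1127 at day 3 and 454 at day 7, with 100 and 69 higher (median log2 fold change -1.61 and -0.87, adjusted p = 0.0187 and 0.0394 with an estimated correlation), again on a group defined by these vein libraries. Nerve-enriched genes went both ways at day 3, with 427 of 1485 higher and 365 lower, and at day 7 with 400 higher, 119 lower and 966 not called (adjusted p = 0.669 and 0.0394 with an estimated correlation), on a group selected as lower in vein. In all, 4255 genes were higher and 4092 lower than in vein at day 3, and 2401 and 2147 at day 7. ENSRNOG00000043451, a nerve-enriched gene, stood at 2219.5 CPM ± 1534 in EV at day 3 and 0.375 CPM ± 0.157 in vein (SD, n = 3 each; edgeR adjusted p = 1.26e-08). ENSRNOG00000003510 stood at 525 CPM ± 147 in vein and 5.65 CPM ± 2.35 in EV at day 7 (SD, n = 3 each; log2 fold change -6.54 ± 0.59 SE, edgeR adjusted p = 5.79e-07).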

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

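Chosen only after the result was seen were the tests of genes above the healthy muscle level, of scaling, of implied shares per library, of both explanations for the vein-enriched share and of an EV library under the label, as were the contrast over both days and the block at day 7. Among the 17 measures tested in the 5 healthy nerves, 2 stood out by the gap of 1 library from the rest, where chance gives about 1 in 20. Healthy nerve replicate 5 had 4.25% of its counts in repair-induced genes, with the next at 3.07% and the lowest at 2.62%. Healthy nerve replicate 2 had 2.04 CPM of the vein-enriched gene ENSRNOG00000034290, with the next at 0.497. The MIV effect on the nerve-enriched share differed between days by -1.61 percentage points (exact permutation within days, p = 0.015), positive at day 3 (0.670) and negative at day 7 (-0.937). It did not pass adjustment over the 5 gene groups (adjusted p = 0.075), and outside muscle-enriched genes the p was 0.08.

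The first pattern is the rise of muscle-enriched genes in MIV. Under carry-over of healthy muscle RNA in its own proportions each gene implies the same share of it, and the median implied share was 10.8% over the 157 genes that rose and 2.51% over the 100 muscle-enriched genes most abundant in healthy muscle, a ratio of 4.30 on the mean of the MIV groups, inside the 10-fold bound set beforehand, but 4 of the 6 MIV libraries exceeded it: the ratio was 11.4, 26.2 and 41.8 in MIV day 3 replicates 1, 2 and 3, and 3.48, 11.6 and 3.15 in the day 7 replicates, while in 3 of those 4 the quartiles of the abundant genes spanned 0. Levels were CPM scaled with TMM factors (0.41 to 0.42 in healthy muscle, 1.07 to 1.21 in the MIV libraries). Implied shares therefore run lower than shares of unscaled counts. Since the 157 genes were chosen for a higher level in MIV, which raises their implied share, and the 100 were not, the ratios decide nothing either way. For the 157 genes as a set, carry-over therefore cannot be told apart from altered expression in the grafted muscle, which was not tested directly. Called higher in MIV than in healthy muscle were 11 genes (7.01% of the 157, against a bound of 5%). With factors from the other genes all 11 kept a positive log2 fold change (median 2.62 against 2.93), and 7 (4.46%) stayed called. The shares of 7.01% and 4.46% lie on either side of the bound, so that rule decides nothing. For those 7, log2 fold changes of 2.58 to 4.05 with these factors (SE 0.66 to 1.42) argue against carry-over in healthy muscle's proportions as the only source. The same values in the same MIV libraries chose these 7 genes, so they are no independent test. The set is not settled by these 7 genes, since 124 of the 157 genes were lower than in healthy muscle. Scaling is argued against for the rise itself, since 163 muscle-enriched genes rose with factors from the other genes, and for the 7 genes that stayed called. It is not argued against for the other 4. Their log2 fold changes against muscle stayed positive but fell from between 0.71 ± 0.24 and 2.74 ± 1.12 to between 0.37 ± 0.23 and 2.44 ± 1.13 (SE). Their adjusted p (edgeR) went from at most 0.0476 to at least 0.0673.

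The second pattern is the lower vein-enriched share in MIV over both days. It rests mostly on day 7, with a difference of -3.21 percentage points (exact permutation p = 0.1) against -0.622 at day 3 (exact permutation p = 0.4). Dilution by muscle counts alone is argued against: outside muscle-enriched genes the difference was -1.75 percentage points (exact permutation within days, p = 0.02), close to the -1.92 over all counts. A single MIV library is argued against too, since the difference was still -1.61 without MIV day 7 replicate 3, the omission that shrank it most. What remains open is a difference between the repairs themselves, which was not tested, and the p does not pass adjustment over the 5 gene groups (0.1).

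The third pattern is MIV day 7 replicate 2, which correlated at 0.874 to 0.903 with the other 2 libraries of its group and held 21.8% of its counts in repair-induced genes. An EV library under its label is argued against: of 129 muscle-enriched genes called higher in MIV without this library and at or under 1 CPM in EV, 91 (70.5%) lay above every EV library in it, against at most 24.8% for an EV library over the other 5. An MIV day 3 library under its label is argued against as well: on 2462 genes outside the muscle-enriched group that changed between the EV days, with 0 at the EV day 3 mean and 1 at the EV day 7 mean, it scored 0.672, against -0.0212 to 0.0816 for the MIV day 3 libraries and 0.847 and 0.936 for the other MIV day 7 libraries. Without its 10 genes with the most counts the repair-induced share was 14.9%, above the next highest repaired library (13.5%). By the rule set beforehand, a share above every other repaired library argues against a few abundant genes as the source. The excess was less than the SD of the others (2.002), a margin that was added after the value had been seen. With that margin a few abundant genes cannot be told apart from a broader change. A difference between the nerves in the course of repair stays open and was not tested.

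Other splits of the same libraries were refitted. For the contrast of MIV and EV over both days, 1 of 100 splits within days, the real one, gave as many genes (232, highest other 2). The other splits were a random draw from those possible. This argues against chance for the contrast as given. It does not cover the choice of this contrast after the separate days had been examined. The count was also 0 without EV day 3 replicate 1 or 3 or EV day 7 replicate 1 or 3. Chance is therefore not excluded. For the comparisons with healthy nerve, refitted on the 2 groups, 1 of 56 splits, the real one, gave as many, which argues against chance. The highest other count was 1 for EV day 3 (9822 real), 0 for EV day 7 (8543), 1 for MIV day 3 (10028), 1 for MIV day 7 (7593), 0 for muscle (10781) and 1 for vein (7901). For the difference of the MIV effect between days, all 100 splits gave at least the 0 genes of the real one (highest other 2), which a real count of 0 fixes in advance, so this test cannot bear on chance. With 3 against 3 the 10 splits are too few for a share under 0.05. All 10 gave at least the 0 genes called between MIV and EV at day 3 and at day 7 (highest other 1 each), again fixed by a real count of 0. At day 7, where the numbers met the limit for pairs, 4 splits part all 3 pairs: with the block the real one gave 43 genes and the highest other 0, and the 6 splits that part 1 pair gave at most 1. The block was chosen from deviations around the real group means, which favours the real split, so these counts are no independent test. The day contrasts gave 2947 in EV (highest other 0) and 2327 in MIV (highest other 241). The other fits of 3 against 3 gave a highest other of 0: MIV against muscle 9685 and 8102, EV against vein 7848 and 5218, and muscle against vein 9882.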

How the results depend on the processing

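The voom alternative, the block at day 7 alone and all values for MIV against EV over both days were chosen after seeing the data; the other alternatives were planned. Under the alternatives that were not left-out libraries, 119 values stayed within 1.5 times of the reported count (or within 1 SD for shares) and 28 did not. All comparisons with healthy tissues kept their counts within 1.5 times under every alternative run, each left-out library included, and RLE factors, the missing count filter and TMM factors from other genes moved no count that far. The cause of the shifts below was not tested, except that a stricter group definition leaves fewer genes in the group by construction.

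DESeq2 called 239 genes between MIV and EV at day 3 (115 outside the muscle-enriched genes) and 824 at day 7 (326 outside), 3607 between the MIV days, 16 for the difference of the MIV effect between days and 820 for MIV against EV over both days. With all 23 libraries in 1 fit, edgeR called 160 at day 3 (70 outside), 1135 at day 7 (452 outside), 4533 between the EV days, 4153 between the MIV days and 975 over both days. This fit may understate the spread of the repaired nerves. Voom with quality weights (limma) called 30 at day 3 (25 outside), 414 at day 7 (109 outside), 6388 between the EV days, 5263 between the MIV days and 480 over both days; it gave MIV day 7 replicate 2 the lowest weight, 0.185. With the 2 groups alone the MIV days gave 804. Log2 fold thresholds of 2 and 3 left 1430 and 810 muscle-enriched genes.

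Leaving out 1 library at a time, the counts ran from 0 to 70 for MIV against EV at day 3 (0 to 28 outside the muscle-enriched genes), from 0 to 688 at day 7 (0 to 151 outside), from 0 to 3 for the difference between days, from 0 to 698 over both days, from 1390 to 4030 between the EV days and from 804 to 3569 between the MIV days. MIV day 7 replicate 2 gave the highest value in each case, EV day 3 replicates 1 and 3 and EV day 7 replicates 1 and 3 gave 0 over both days, and EV day 3 replicate 2 and MIV day 3 replicate 3 gave the lowest for the EV and MIV days. The day 3 difference in muscle-enriched share ran from -0.107, without MIV day 3 replicate 1, to 1.73, and the day 7 difference from 4.61 to 14.3.

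By the limit of 0.1, replicate numbers paired the EV and MIV libraries at day 7 and no other groups. Over all same-numbered repaired libraries the mean correlation of deviations was 0.0361 (lowest -0.151, 6 of 18 pairs above 0.1). Over different-numbered libraries it was -0.0181 (highest 0.276, 8 of 36 pairs above 0.1), and 5 of 12 libraries correlated best with their own number. Pairing at day 7 is therefore uncertain. With the number as a block at day 7 alone, edgeR called 43 genes between MIV and EV at day 7 (15 outside the muscle-enriched genes), or 4 with the 2 groups alone; over both days it gave 211 calls, ending 58 of the 232 and adding 37, and among gene sets only the nerve-enriched set at day 7 with fry changed. Within the 3 pairs the day 7 differences had one sign for the muscle- and vein-enriched shares (exact sign-flip p = 0.25 for both, the smallest possible). With the number as a block over both days, MIV against EV over both days gave 109 calls and each other count stayed within 1.5 times. The gene-list results and their alternatives were not run, because no identifier matched a symbol. Of simulated 2-fold changes between MIV and EV at day 7, in genes above a minimum mean level in both groups, 11.9% were recovered.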

Other observations

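The hypothesis below was formed, and the tests of genes above the healthy muscle level and of implied shares per library chosen, after the results had been seen. The implied shares of healthy muscle, on CPM scaled with TMM factors, differed widely between the MIV libraries. These factors were 0.41 to 0.42 in healthy muscle and 1.07 to 1.21 in MIV. The values therefore run lower than shares of unscaled counts and are not amounts of muscle RNA. Over the 100 muscle-enriched genes most abundant in healthy muscle, the median implied share was 9.41% in MIV day 7 replicate 3 and 3.18% in replicate 1, but 0.0790% in replicate 2, and it was 0.893%, 0.0806% and 0.0294% in MIV day 3 replicates 1, 2 and 3. Over the 157 muscle-enriched genes that rose in MIV, the medians were 29.6%, 11.1% and 0.916% in MIV day 7 replicates 3, 1 and 2, and 10.2%, 2.11% and 1.23% in the MIV day 3 libraries 1, 2 and 3. Of the 157 genes, 35, 21 and 7 stood above their healthy muscle level in MIV day 7 replicates 3, 1 and 2, and 23, 17 and 15 in MIV day 3 replicates 1, 2 and 3. None of the 100 abundant genes did so in any MIV library, but they were chosen for the highest levels in healthy muscle, which by itself favours this outcome.

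The 157 genes were chosen for a higher level in MIV and the 100 were not, which by itself widens the gap between the 2 sets. One hypothesis is that part of the muscle signal may come from muscle that had changed its expression, rather than from intact muscle. The 11 genes above the healthy muscle level prompted it. All 11 kept a positive log2 fold change against muscle with factors from the other genes, and 7 stayed called. For those 7 the levels argue against carry-over in healthy muscle's proportions as the only source, although the same levels chose them. Those 7 genes do not settle the hypothesis for the 157 genes. The ratio of implied shares (4.30 on the mean of the MIV groups) stayed inside the 10-fold bound set beforehand but was beyond it in 4 of the 6 MIV libraries, and the choice of genes raises it, so it supports neither side. Without gene names the set could not be compared with known programmes of muscle regeneration.

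Of the 57 rises over both days in MIV outside the muscle-enriched genes, 15 reached 10 CPM without overlap between the libraries, and among these ENSRNOG00000006142 and ENSRNOG00000061038 had the largest. ENSRNOG00000006142 stood at 93.7 CPM ± 109 in MIV and 0.124 CPM ± 0.213 in EV (SD, n = 6 each; edgeR adjusted p = 0.0110; 183 to 3599 counts per MIV library), with 1.004 CPM in healthy muscle and none in nerve or vein. ENSRNOG00000061038 stood at 22.9 CPM ± 35.0 in MIV and 0.0123 CPM ± 0.0302 in EV (SD, n = 6 each; edgeR adjusted p = 0.0180; 28 to 1076 counts per MIV library), with 0.324 CPM in healthy nerve and 0.275 CPM in healthy muscle.

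On the 2462 genes outside the muscle-enriched group that changed between the EV days (2947 changed in all), the 5 healthy nerves scored 1.12 to 1.15 and the 3 healthy veins 1.22 to 1.23, beyond the EV day 7 mean of 1, and the 3 healthy muscles scored 0.690 to 0.756, below it. The score follows only the difference between the EV days and does not measure closeness to healthy tissue. At day 7, 3841 genes were still higher and 3822 lower in EV than in healthy nerve.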
